A study of Arabidopsis thaliana with 19 samples.

How the data were processed

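RNA was measured in cells sorted from shoot apices of Arabidopsis thaliana plants carrying the ap1-1 and cal1-1 mutations and grown for 28 days. In these plants the shoot tip makes many meristems in place of flowers. Per the labels, apices were turned into protoplasts and cells carrying a fluorescent promoter reporter were sorted. Per the series design, RNA was amplified in 2 rounds before hybridisation. Biotin-labelled cRNA was hybridised to Affymetrix ATH1 arrays, on which a probe set of short oligonucleotides stands for a transcript.

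The deposited intensity values were linear, single-colour MAS5 signals per probe set, scaled by the authors. MAS5 is named in the submitters' processing notes, and its version was not given in the sources used here. Checked on the values, the mean of each array after trimming 2% at each end was 500, which is a scaling of every array to 1 target. The authors' deposited table of averaged intensity held the mean per reporter of the same arrays, within 0.005 of the means computed here, together with detection calls (P, present, M, marginal, or A, absent) per array and a locus for 21021 probe sets. Scanner files and scan dates were not used here, and the number of arrays limits the precision. No replicate pair held identical values.

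Groups were taken from the sample labels: 19 arrays in 7 reporter populations, with 2 arrays for AtML1 and LAS and 3 for the others. AtML1 and HMG are both labelled epidermal, HDG4 subepidermal, KAN1 organ circumference, LAS adaxial, AtHB8 xylem (with the word stem in its label) and S17 phloem. No control sample was among them, so each of the 6 labelled cell types was compared with an equally weighted mean of the other reporters, and 4 comparisons were made between populations. The sources used here do not give the gene behind the HMG reporter. The gene of the S17 reporter was taken from background knowledge as BZIP6.

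Of 22810 probe sets, 64 were controls and were left out. A probe set was tested where its signal was at or above the 40th percentile of its own array on all arrays of at least 1 reporter, which kept 15149 of 22746. Tests were made on log2(signal + 1) with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 mean per reporter over all 19 arrays and empirical Bayes moderation (12 residual and 3.07 prior degrees of freedom). Folds are therefore on the log2(signal + 1) scale, and the added 1 shrinks the differences of dim genes. Signals of probe sets called absent still enter the log2 differences, which can therefore lie above the bounds described below. All limma tests were two-sided. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. Any difference among the 7 reporters was tested with limma's moderated F test. Adjusted p-values of single genes in the text come from limma.

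Where a probe set was called absent on every array of a dimmer group, its difference is only a bound. There the text gives "at least N-fold", the brighter mean over the mean of, per array, the higher of the dim signal and the lowest signal among probe sets called present, with the adjusted p of the test. These are means of log2(signal + 1), taken per reporter and then over reporters, so folds and bounds are ratios of geometric means. No fold is given where that bound lies under 1. The lowest present signal is no limit of detection, as probe sets called absent could lie higher. On HMG replicate 1 it was 37.4, while HDG4, called absent, was at 88.8. The bounds are therefore approximate, and they leave out the error of the means. A fold against the rest can lie far above the ratio of arithmetic means where 1 reporter of the rest is high and the others are dim, and such a reporter can exceed the population compared. The ratio of arithmetic means, each reporter weighing the same, was therefore computed for the named genes after seeing the data.

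There were 17 gene lists with 283 genes, 266 of them with a probe set. They covered epidermal identity, cuticle and wax, photosynthesis, organ boundary, abaxial and adaxial fate, meristem, floral regulators, procambium and early xylem, xylem secondary wall, phloem, cell division, auxin, cytokinin, stress and wounding, stomatal lineage and HMG box genes. The stress and wounding list, of heat, touch and wound or jasmonate genes, was set as a mark of the protoplasting. Its shifts are not separated here from the handling of the cells. Each gene was represented by its probe set in the authors' averaged table, which held 21021 probe sets for 21021 loci. Each list was tested in each of 10 comparisons with limma's camera at a preset correlation of 0.01, adjusted over 170 tests, and again with an estimated correlation and with fry. Members called are counted over all probe sets tested, and the count adjusted over the list alone is given wherever it differed. ATML1, ATHB8, LAS and BZIP6, which are reporter genes, are also members of lists.

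The groups, comparisons, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took, for each comparison with the rest, the reporter's gene, the 10 highest and 5 lowest differences among called probe sets whose arrays did not overlap with those of the other populations, and up to 4 members of each list with the smallest p. For comparisons between populations it took 5 genes in each direction and the same list members.

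Gene names follow the locus in the authors' averaged table and the symbols of the TAIR10.1 RefSeq table, in which 20776 of the 21021 loci were found. The platform table paired 13513 probe sets with 1 gene and 503 with several, and did not list 8794, which were named through the averaged table where it held them. Among tested probe sets, 992 had no nameable gene and were left unnamed. The genome build was not given in the sources used here, and no coordinates are printed.

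The procedure was tested on simulated arrays of 15149 probe sets, each with its real mean shared by all populations and its real spread within populations. For each comparison 200 probe sets were changed. At 8-fold, between 92.4% (organ circumference against adaxial) and 100% (epidermis against the rest) of the changed probe sets were called. At 4-fold the share ran from 82.1% (AtML1 against HMG) to 98.5% (phloem against the rest), and at 2-fold, which is the threshold itself, from 26.9% (epidermis against subepidermis) to 47.8% (xylem against the rest). Per comparison 1 to 9 unchanged probe sets were called, and 0 changed ones in the wrong direction. The simulated spread was drawn independently for each probe set and array. These rates therefore do not cover a spread that genes of an array share.

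RNA quality was measured as the ratio of 3' to 5' control probe set signals for ubiquitin, actin and GAPDH, and compared by two-sided exact permutation tests, with Benjamini-Hochberg adjustment over 6 tests. These tests were not among those fixed beforehand. They exchange single arrays and not reporters, so their p-values do not measure the spread between reporters. Alternatives were quantile normalisation, centring on the array median, no filter or the 60th percentile, a pseudocount of 32, trended and robust moderation, array weights, the replicate number as a block, leaving out each array, no fold minimum, another weighting of the rest, and fits of only the arrays compared. Another 3 were chosen after seeing the data. These were a rest without the vascular reporters, a filter on detection calls, and leaving out the 3 arrays with the highest actin ratio.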

Results

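Transcript levels were compared between 7 populations of fluorescent cells sorted from Arabidopsis shoot apices, on 19 arrays. The reporters mark the epidermis (AtML1, n = 2, and HMG, n = 3), the layer beneath it (HDG4, n = 3), the circumference of organs (KAN1, n = 3), the adaxial side (LAS, n = 2), xylem (AtHB8, n = 3) and phloem (S17, n = 3). Median signals of the arrays lay between 152 and 183. Between 53.8% (AtML1) and 58.3% (S17) of the probe sets in the averaged table were called present on all arrays of a reporter. The labels do not say whether replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

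Arrays of the same reporter resembled each other more than arrays of different reporters, and these tables do not separate cell type from the reporter line and its sort. Of 15149 tested probe sets, 11399 differed among the 7 reporters (moderated F test). Arrays of the same reporter correlated with a median r of 0.956 across genes (17 pairs), and genes are not independent replicates. The vascular reporters AtHB8 and S17 correlated with each other at 0.881 (9 pairs) and with the remaining reporters at 0.675 (78 pairs), against 0.888 among the remaining reporters (67 pairs). AtML1 and HMG arrays correlated at 0.922, KAN1 and epidermal arrays at 0.891, LAS and HDG4 arrays at 0.906, and epidermal and HDG4 arrays at 0.871. On principal components, the first component held 56.0% of the variance.

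**Figure D1:**
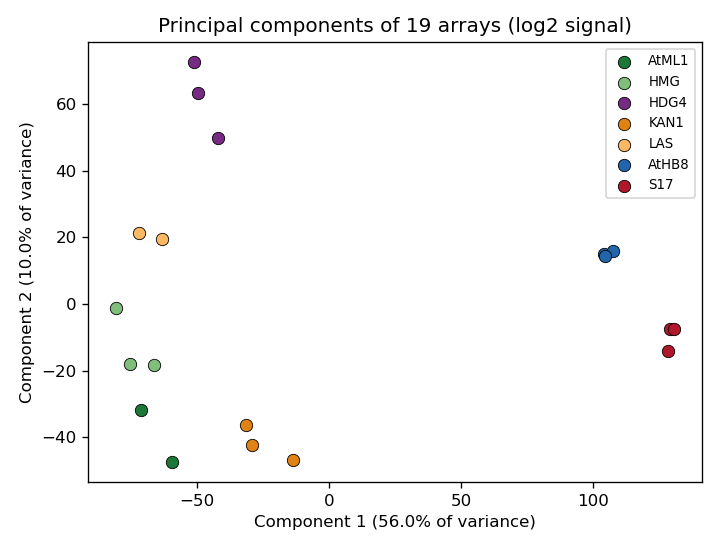
Each point is an array, placed by the principal components of its log2 signals (axes in percent of variance) and coloured by reporter. The AtHB8 and S17 arrays lie apart from all others along the first component, which holds 56.0% of the variance.

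The reporters' own genes were examined as a check of the labels. ATML1 (AT4G21750), a homeodomain regulator of epidermal identity, had a mean signal of 7336 ± 41.3 (SD, n = 2) in AtML1 and 8595 ± 1534 (n = 3) in HMG, against 332 in HDG4, 97.3 in AtHB8 and 118 in S17. It was also high in KAN1, at 5223 ± 228 (n = 3), and in LAS, at 3180 ± 1003 (n = 2). ATHB8 (AT4G32880), a class III HD-ZIP factor of the procambium, reached 9303 ± 1070 in AtHB8 and 1714 ± 264 in S17 (n = 3 each), and was called absent on every other array. LAS (AT1G55580), a GRAS regulator of axillary meristems, reached 5973 ± 92.1 in LAS (n = 2) and at most 199 elsewhere. BZIP6 (AT2G22850) was highest in S17, at 318 ± 53.2, and next in AtHB8, at 128 ± 32.4. KAN1 (AT5G16560) was dim, with 103 ± 36.5 in KAN1 and 97.7 ± 19.7 in S17 (n = 3 each), and HDG4 (AT4G17710) was called absent on all 19 arrays. Neither passed the filter, so these genes do not check the KAN1 and HDG4 labels.

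**Figure D2:**
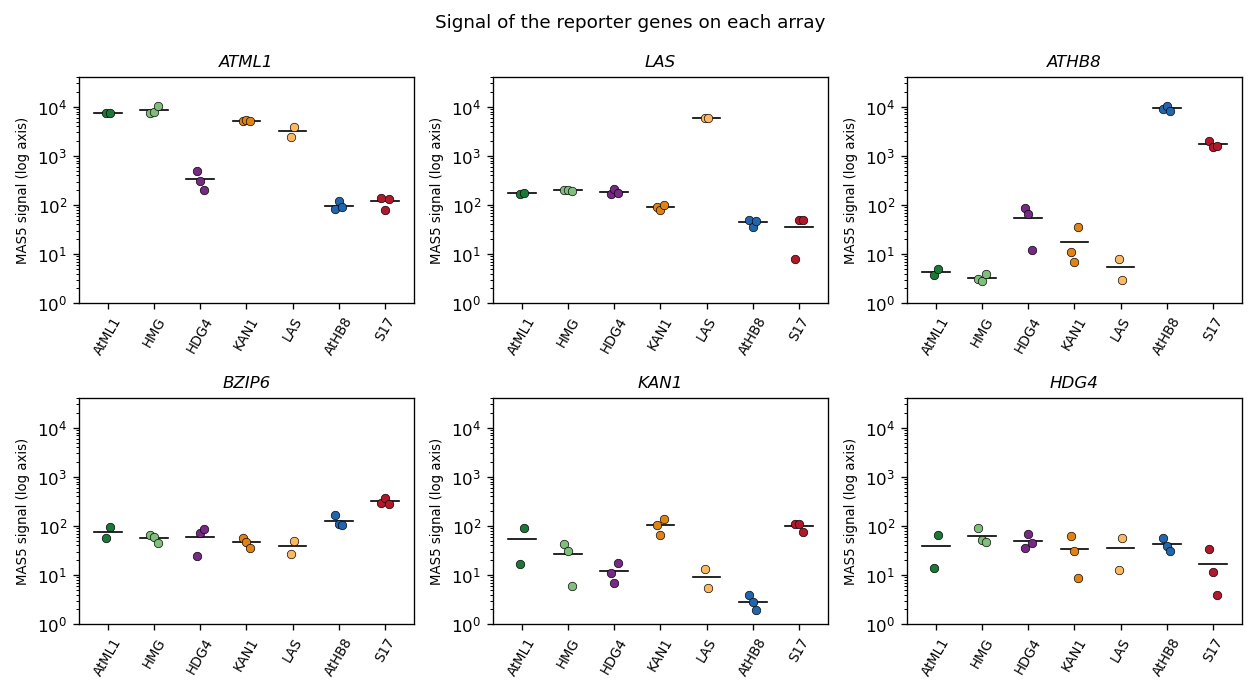
MAS5 signal (log axis) of the genes of 6 reporters on each array, grouped by reporter, with lines at the means. LAS and ATHB8 are highest in the population named for them, ATML1 is high in AtML1, HMG, KAN1 and LAS, and HDG4 stays low on every array.

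Epidermal cells (AtML1 and HMG, n = 5) were set against the other reporters to find epidermal transcripts. Folds and bounds here and below are ratios of geometric means. OFP15, an Ovate family gene, had the highest difference among genes whose arrays did not overlap with those of the other populations, at least 15.0-fold (log2 5.12 ± 0.36 SE, adjusted p = 4.05e-08), and genes of wax and cuticle synthesis were among the 10 highest. KCS8 (AT2G15090), a fatty acid elongase, was 20.9-fold higher (log2 4.39 ± 0.14, adjusted p = 1.25e-11), and the elongase KCS2 at least 15.0-fold. MYB30, a regulator of very-long-chain fatty acid genes, was at least 15.0-fold higher (log2 4.53 ± 0.45, adjusted p = 1.84e-06). All 18 tested cuticle and wax genes were higher, among them FDH 19.7-fold, KCS1 18.6-fold and HTH 9.89-fold (log2 3.31 ± 0.10, adjusted p = 9.15e-12). The list passed camera with an adjusted p = 1.4e-19 (adjusted p = 0.000497 with an estimated correlation). Of 11 epidermal identity genes 9 were higher, with ATML1 14.1-fold (log2 3.81 ± 0.20, adjusted p = 1.45e-09), LTP1 10.2-fold, PDF1 10.1-fold and the receptor kinase ACR4 at least 7.35-fold (camera adjusted p = 3.33e-09, and adjusted p = 0.0191 with an estimated correlation).

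Several vascular genes were low in the epidermis. BAM3, a receptor kinase of early phloem, was at least 23.9-fold lower (log2 -6.53 ± 0.36, adjusted p = 2.94e-09), and RUL1, a receptor-like kinase of the cambium, at least 9.83-fold lower (log2 -5.83 ± 0.23). TMO5, a bHLH factor of vascular initials, was at least 9.54-fold lower and PXY, the receptor for the cambial peptide TDIF, at least 13.2-fold. Of 10 procambium and early xylem genes 7 were lower (camera adjusted p = 1.7e-06, adjusted p = 0.0537 with an estimated correlation). Of 23 phloem genes 15 were lower (adjusted p = 3.06e-06, and adjusted p = 0.0247 with an estimated correlation), and of 11 xylem secondary wall genes 6, or 7 adjusted over the list alone (adjusted p = 0.00306, adjusted p = 0.253 with an estimated correlation). Organ boundary genes were higher in 8 of 14 cases, as with BOP1, a co-regulator of leaf and flower patterning, at least 7.60-fold (adjusted p = 6.45e-05, and adjusted p = 0.0273 with an estimated correlation). Floral regulators were higher in 5 of 12 cases, among them SEP2 at least 14.1-fold and UFO at least 4.18-fold (adjusted p = 0.0019, adjusted p = 0.0529 with an estimated correlation). AP1 was 2.51-fold higher, and its signal is the transcript of the mutant allele these plants carry.

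Photosynthesis genes were lower in 4 of 22 cases, with PRK, a Calvin cycle kinase, 3.34-fold (adjusted p = 0.00221, adjusted p = 0.561 with an estimated correlation). Of 4 stomatal lineage genes, 2 were higher, with the protease gene SDD1 at least 3.11-fold, and the list did not pass (adjusted p = 0.632). HMGB15, of the HMG box list, was at least 15.6-fold higher (log2 4.25 ± 0.38), while the list did not pass (2 of 12 higher, adjusted p = 0.0947). By arithmetic means, chosen after seeing the data, the ratios to the rest were smaller for genes that were also high in KAN1, LAS or HDG4. They were 4.45 for ATML1, 3.42 for LTP1, 3.25 for PDF1, 4.28 for ACR4, 3.98 for HTH, 5.78 for KCS1, 4.97 for KCS2, 7.49 for KCS8 and 5.66 for FDH. OFP15 was at 5.70, MYB30 at 6.19, SEP2 at 8.14 and UFO at 1.75, with UFO higher in HDG4. In all, 713 probe sets were higher and 1205 lower. Without the vascular reporters in the rest, a choice made after seeing the data, 968 were called, of which 53.8% were higher, against 37.2% with them. In that setting the named differences were smaller, and the following stayed called. Higher were ATML1 (log2 2.20), OFP15 (3.04), MYB30 (2.28), KCS2 (2.40), KCS8 (2.95), KCS1 (2.50), FDH (2.54), HTH (1.75), ACR4 (adjusted p = 3.49e-06), LTP1 (1.78), PDF1 (1.64), BOP1 (2.11), UFO (1.00) and SEP2 (2.81). Lower were RUL1 (-3.65), TMO5 (-3.57), PXY (-2.57) and BAM3 (-4.28). There AP1 (log2 0.94) fell short of the 2-fold minimum. The photosynthesis list (adjusted p = 0.484) and the xylem secondary wall list (adjusted p = 0.979) did not pass. Nor did the xylem secondary wall list with the 60th percentile filter (adjusted p = 0.177).

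Subepidermal cells (HDG4, n = 3) had higher levels of several cell division genes and of a few sieve element genes. Of 22 cell division genes 9 were higher, among them the mitotic cyclin CYCB1;1 3.29-fold (log2 1.72 ± 0.17 SE, adjusted p = 4.3e-06) and PCNA2, a replication clamp, 2.50-fold (camera adjusted p = 1.06e-07, adjusted p = 0.166 with an estimated correlation). SEOR1, which encodes a filament protein of sieve elements, was at least 17.8-fold higher (log2 4.40 ± 0.56, adjusted p = 4.64e-05), SEOR2 at least 8.62-fold, and APL, a MYB regulator of phloem identity, at least 4.65-fold (log2 3.47 ± 0.48). The phloem list as a whole did not pass, with 5 of 23 higher and 2 lower (adjusted p = 0.63), and SWEET12, a sucrose exporter, was at least 3.66-fold lower. UFO, an F-box regulator of floral organs, was at least 9.46-fold higher (log2 3.38 ± 0.27, adjusted p = 7.87e-07), and PI, a petal and stamen identity gene, 3.68-fold. ACC2, a plastid acetyl-CoA carboxylase, was higher with a log2 difference of 4.25 ± 0.30 (adjusted p = 3.06e-07), and HDG7, a homeodomain gene, at least 4.62-fold. By arithmetic means, chosen after seeing the data, the ratios to the rest were 8.34 for SEOR1, 6.36 for SEOR2, 3.33 for APL and 5.34 for UFO, and APL was higher in S17 (301) than in HDG4 (202).

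Photosynthesis genes were lower in 17 of 22 cases, with LHCB3 3.79-fold and LHCB6 2.64-fold lower (camera adjusted p = 2.27e-12, adjusted p = 0.179 with an estimated correlation). Cuticle and wax genes were lower in 11 of 18 cases, with FDH 4.89-fold (adjusted p = 1.19e-07, and adjusted p = 0.0141 with an estimated correlation). Among epidermal identity genes 5 were lower, with PDF2 7.04-fold and ATML1 4.81-fold, and 2 higher (adjusted p = 0.0128, adjusted p = 0.261 with an estimated correlation). Meristem genes were higher in 6 of 17 cases and lower in 1, with the floral and meristem regulator ULT1 3.52-fold higher (2.20 by arithmetic means) and KNAT1 2.16-fold lower (adjusted p = 0.0197, adjusted p = 0.336 with an estimated correlation). HMG box genes were higher in 5 of 12 cases, as with 3XHMG-BOX2 2.78-fold (adjusted p = 0.0296, adjusted p = 0.282 with an estimated correlation). Xylem secondary wall genes were lower in 6 of 11 cases, or 7 adjusted over the list alone (adjusted p = 0.00282, adjusted p = 0.25 with an estimated correlation), and stress and wounding genes in 3 of 20, with the jasmonate enzyme LOX3 2.21-fold (adjusted p = 0.000307, adjusted p = 0.235 with an estimated correlation). The auxin importer LAX2 was 6.33-fold lower. In all, 615 probe sets were higher and 1284 lower. With no fold minimum 2990 were higher and 2499 lower, so the larger side turned. A total of 1196 were called without the vascular reporters in the rest, a choice made after seeing the data. In that setting PDF2 (log2 -4.77), ATML1 (-4.18), FDH (-4.39) and SEOR1 (5.17) differed more, and UFO (2.38), SWEET12 (-1.55), CYCB1;1 (1.09) and LAX2 (-2.04) less. SEOR2 was at log2 4.13 with the replicate block, against 3.45. Without the vascular reporters ULT1 (log2 0.68), PI (0.97), PCNA2 (0.54), KNAT1 (-0.28) and LOX3 (-0.45) fell short of the 2-fold minimum. The meristem (adjusted p = 0.166), HMG box (adjusted p = 0.419), xylem secondary wall (adjusted p = 0.401) and stress and wounding lists (adjusted p = 0.0511) did not pass. With the 60th percentile filter the meristem (adjusted p = 0.27), HMG box (adjusted p = 0.139) and xylem secondary wall lists (adjusted p = 0.263) did not pass. The HMG box list did not pass either with array weights (adjusted p = 0.0574), with the replicate block (adjusted p = 0.0809), without the 3 arrays of highest actin ratio (adjusted p = 0.0533) or without HDG4 replicate 4 (adjusted p = 0.0625). Without HDG4 replicate 3 the meristem list did not pass (adjusted p = 0.068).

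Cells of the organ circumference (KAN1, n = 3) were set against the other reporters. LTP1, a lipid transfer protein, was 6.68-fold higher (log2 2.74 ± 0.20 SE, adjusted p = 4.74e-07), PDF1 6.22-fold and KCS1 6.13-fold. PRK was 3.35-fold higher (log2 1.74 ± 0.16, adjusted p = 3.26e-06), and GAPB, another Calvin cycle enzyme, 3.74-fold. STM, a homeodomain gene that maintains meristems, was 3.58-fold lower (log2 -1.84 ± 0.11, adjusted p = 1.47e-07), and the class III HD-ZIP genes PHB and REV, which set adaxial fate, 3.78-fold and 3.05-fold. LOG4, a cytokinin-activating enzyme, was 5.67-fold lower (log2 -2.50 ± 0.18). Among the highest differences were the phospholipase gene PLA2-ALPHA, at least 11.9-fold (log2 4.62 ± 0.35), GH3.17, which encodes an auxin-conjugating enzyme, at least 18.7-fold, and the carbonic anhydrase CA1, at least 19.8-fold. By arithmetic means, chosen after seeing the data, the ratios to the rest were 2.26 for LTP1, 2.10 for PDF1, 1.53 for KCS1 and 11.5 for GH3.17. AtML1 exceeded KAN1 in LTP1 and PDF1, HMG in KCS1, and S17 in PRK. Of 32 genes that the naming rule took and that were called higher, 14 had a ratio under 2. In 16 of the 32, another reporter exceeded KAN1.

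Cuticle and wax genes were higher in 15 of 18 cases, or 16 adjusted over the list alone (camera adjusted p = 6.34e-16, and adjusted p = 0.000959 with an estimated correlation). Epidermal identity genes were higher in 7 of 11 (adjusted p = 6.09e-06, adjusted p = 0.0529 with an estimated correlation), and photosynthesis genes in 14 of 22, or 15 adjusted over the list alone (adjusted p = 1.74e-14, adjusted p = 0.157 with an estimated correlation). Adaxial genes were lower in 5 of 6 cases (adjusted p = 2.03e-05, adjusted p = 0.0529 with an estimated correlation). Of 10 cytokinin genes 2 were lower (adjusted p = 0.0087, adjusted p = 0.112 with an estimated correlation). Cell division genes were higher in 5 of 22 cases and lower in 1 (adjusted p = 0.00114, adjusted p = 0.373 with an estimated correlation). Lower shifts were found for xylem secondary wall genes (3 of 11 lower, adjusted p = 0.00218, adjusted p = 0.235 with an estimated correlation), procambium and early xylem genes (2 of 10, or 3 adjusted over the list alone, adjusted p = 0.00112, adjusted p = 0.179 with an estimated correlation) and stress and wounding genes (1 higher and 1 lower of 20, adjusted p = 0.0398, adjusted p = 0.471 with an estimated correlation). Abaxial genes did not pass (1 of 6 higher and 1 lower, adjusted p = 0.808), with FIL, a YABBY gene of abaxial fate, 2.67-fold higher (1.38 by arithmetic means, with HDG4 above KAN1). The lower member was KAN3, at log2 -1.93, and at -2.68 without KAN1 replicate 1.

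In all, 766 probe sets were higher and 378 lower around the organ circumference. The actin 3' to 5' ratio was 5.50 ± 0.918 (SD, n = 3) on KAN1 arrays and 11.8 ± 3.58 (n = 16) on the others (exact permutation p = 0.0114, adjusted p = 0.0341). KAN1 had the lowest mean of all reporters, and the adjustment does not cover a choice among reporters. With the vascular reporters left out of the rest, a choice made after seeing the data, LTP1 (log2 1.28), PDF1 (1.08), PLA2-ALPHA (4.02) and GH3.17 (3.58) were still called, with smaller differences, and PRK (2.42) and GAPB (2.58) differed more. ATML1 (0.91), KCS1 (0.91), FDH (0.71), HTH (0.63) and FIL (0.29) fell short of the 2-fold minimum. In that setting the cuticle and wax list passed (adjusted p = 0.000584), the epidermal identity list (adjusted p = 0.371), the cell division list (adjusted p = 0.986) and the xylem secondary wall list (adjusted p = 0.712) did not. The shifts of the procambium list (adjusted p = 0.243) and the stress list (adjusted p = 0.466) turned upward. The xylem secondary wall list did not pass with the 60th percentile filter (adjusted p = 0.3). The stress list did not pass with that filter (adjusted p = 0.0518), quantile normalisation (adjusted p = 0.063), the replicate block (adjusted p = 0.0518) or fry (adjusted p = 0.096), or without the 3 arrays of highest actin ratio (adjusted p = 0.0837). Single arrays whose removal ended its call were KAN1 replicates 1 (adjusted p = 0.147) and 3 (adjusted p = 0.0668), HMG replicate 1 (adjusted p = 0.067), AtML1 replicate 3 (adjusted p = 0.0546), AtHB8 replicate 3 (adjusted p = 0.0529) and LAS replicate 1 (adjusted p = 0.0583).

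Adaxial cells (LAS, n = 2) were led by LAS itself, at least 58.5-fold higher (log2 5.98 ± 0.41 SE, adjusted p = 4.67e-07). WUS, the homeodomain gene that maintains stem cells, was at least 6.05-fold higher (log2 3.38 ± 0.57, adjusted p = 0.000835), with a signal of 208 ± 2.73 (SD, n = 2), and TEL2, a TERMINAL EAR-like gene, at least 8.49-fold. Boundary genes were higher in 5 of 14 cases, or 8 adjusted over the list alone, among them CUC3 at least 4.99-fold and JLO at least 4.76-fold (camera adjusted p = 5.47e-05, and adjusted p = 0.027 with an estimated correlation). The class I KNOX gene KNAT1 was 3.37-fold lower (log2 -1.75 ± 0.15, adjusted p = 4.22e-06), BAM3 at least 12.0-fold lower, and PUM12, a Pumilio RNA-binding protein gene, at least 11.4-fold lower (log2 -6.15 ± 0.26). By arithmetic means, chosen after seeing the data, the ratios to the rest were 49.6 for LAS, 3.74 for TEL2, 2.67 for CUC3 and 2.94 for JLO. Of 29 genes that the naming rule took and that were called higher, 14 had a ratio under 2. In 14 of the 29, another reporter exceeded LAS.

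Phloem genes were lower in 12 of 23 cases (camera adjusted p = 2.67e-07, and adjusted p = 0.0164 with an estimated correlation), and photosynthesis genes in 7 of 22, or 8 adjusted over the list alone, with PSBO1 2.30-fold lower (adjusted p = 1.7e-06, adjusted p = 0.34 with an estimated correlation). Meristem genes were higher in 5 of 17 cases, or 6 adjusted over the list alone, and lower in 1 (adjusted p = 0.0172, adjusted p = 0.324 with an estimated correlation). Cell division genes were higher in 3 of 22, with PCNA2 2.50-fold (adjusted p = 0.000224, adjusted p = 0.316 with an estimated correlation). Stress and wounding genes were lower in 3 of 20, with LOX3 3.21-fold (adjusted p = 0.000222, adjusted p = 0.222 with an estimated correlation), and auxin genes in 3 of 12, or 4 adjusted over the list alone, with the auxin synthesis gene TAA1 3.84-fold and 1 other member higher (adjusted p = 0.0381, adjusted p = 0.157 with an estimated correlation). The adaxial fate list itself did not pass, with 0 of 6 higher and 1 lower (adjusted p = 0.939).

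Epidermal identity genes were higher in 6 of 11 cases, or 7 adjusted over the list alone (camera adjusted p = 0.00135, adjusted p = 0.161 with an estimated correlation), with ATML1 3.04-fold. Cuticle and wax genes were higher in 6 of 18, or 7 adjusted over the list alone (adjusted p = 0.000285, adjusted p = 0.0529 with an estimated correlation), with HTH 2.66-fold. By arithmetic means neither was higher than the rest (0.879 for ATML1 and 0.958 for HTH), since epidermal cells and KAN1 were above LAS. Procambium and early xylem genes were lower in 5 of 10 (adjusted p = 0.00151, adjusted p = 0.189 with an estimated correlation). With the vascular reporters left out of the rest, a choice made after seeing the data, the cuticle list was shifted lower (adjusted p = 0.000718), ATML1 (log2 -0.03) and HTH (-0.13) were no longer higher, and the shifts of the epidermal identity list (adjusted p = 0.424) and the procambium list (adjusted p = 0.444) turned without passing. In that setting WUS was still called (log2 2.75, adjusted p = 0.0114), as were LAS (5.27), BAM3 (-2.18) and LOX3 (-1.04), with smaller differences. CUC3 (1.01, adjusted p = 0.0743), TEL2 (1.51, adjusted p = 0.0887) and JLO (1.42, adjusted p = 0.103) were not. KNAT1 (-0.96), PSBO1 (-0.96) and PCNA2 (0.54) fell short of the 2-fold minimum. The cell division list (adjusted p = 0.466) and the meristem list (adjusted p = 0.218) did not pass there. A total of 541 probe sets were called in place of 1593 (529 higher and 1064 lower), and with no fold minimum the larger side turned (2003 higher and 1740 lower). JLO was at log2 3.30 without LAS replicate 1, 2.10 without LAS replicate 2 and 3.31 without the 3 arrays of highest actin ratio, against 2.70. Without LAS replicate 1 the higher count was 302, and without LAS replicate 2 the lower count was 691. The auxin list did not pass without LAS replicate 1 (adjusted p = 0.085), without the 3 arrays of highest actin ratio (adjusted p = 0.0533) or with the 60th percentile filter (adjusted p = 0.07). That filter also ended the call of the meristem list (adjusted p = 0.247).

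Xylem cells (AtHB8, n = 3) had high levels of several procambial and xylem genes. ATHB8 was at least 152-fold higher (log2 8.66 ± 0.47 SE, adjusted p = 2e-09), ACL5, a thermospermine synthase that acts in xylem, at least 104-fold, PXY at least 56.3-fold and TMO5 at least 39.8-fold (log2 5.88 ± 0.18). XCP2, a protease of xylem cell death, was at least 35.8-fold higher (log2 5.39 ± 0.68), VND6, a NAC regulator of vessels, at least 10.5-fold, and the secondary wall cellulose synthase gene CESA8 at least 8.22-fold. Of 10 procambium and early xylem genes 9 were higher (camera adjusted p = 5.21e-09, and adjusted p = 0.0266 with an estimated correlation), and all 11 tested xylem secondary wall genes were (adjusted p = 3.06e-06, adjusted p = 0.0765 with an estimated correlation). FAR1 (AT5G22500), a fatty acyl reductase, was at least 32.2-fold lower (log2 -6.44 ± 0.44, adjusted p = 2.42e-08), and ABCG13, a half-size ABC transporter, 43.0-fold. By arithmetic means, chosen after seeing the data, the ratios to the rest were smaller for genes also high in S17. They were 31.0 for ATHB8, 26.2 for ACL5, 28.1 for TMO5 and 18.7 for XCP2, while PXY was at 6286 in AtHB8 and 1868 in S17.

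Auxin genes were higher in 9 of 12 cases and lower in 3, with LAX2 12.3-fold higher and the auxin synthesis gene YUC1 at least 6.60-fold lower (camera adjusted p = 0.0151, adjusted p = 0.1 with an estimated correlation). Stress and wounding genes were higher in 10 of 20 cases and lower in 1, among them the jasmonate catabolic gene CYP94B3 15.6-fold, the heat shock gene HSP101 8.83-fold and LOX3 3.72-fold (adjusted p = 3.68e-06, adjusted p = 0.149 with an estimated correlation). That list was set as a mark of the protoplasting, and handling of the cells is not separated here from cell type. Cuticle and wax genes were lower in 17 of 18 cases, with KCS1 25.4-fold (adjusted p = 2.27e-12, and adjusted p = 0.00269 with an estimated correlation), and epidermal identity genes in 10 of 11, with PDF1 20.5-fold (adjusted p = 6.79e-06, adjusted p = 0.0529 with an estimated correlation). Boundary genes were lower in 11 of 14, or 12 adjusted over the list alone (adjusted p = 2.75e-05, and adjusted p = 0.0253 with an estimated correlation). Cell division genes were lower in 7 of 22 (adjusted p = 0.000403, adjusted p = 0.336 with an estimated correlation), meristem genes in 7 of 17, with 2 higher (adjusted p = 0.0231, adjusted p = 0.34 with an estimated correlation), and HMG box genes in 6 of 12, with HMGB9 at least 14.7-fold (adjusted p = 0.00748, adjusted p = 0.189 with an estimated correlation). Photosynthesis genes were higher in 3 of 22 (adjusted p = 0.0198, adjusted p = 0.647 with an estimated correlation). BAM3, from the phloem list, was at least 24.2-fold higher, but 2.36 by arithmetic means, since S17 was higher than AtHB8 (10722 against 4643). CYP94B3 was at 6.08 by arithmetic means. The phloem list did not pass (9 of 23 higher, 5 lower, adjusted p = 0.194). In all, 1934 probe sets were higher and 1396 lower, and with no fold minimum the larger side turned (3465 higher and 4312 lower). With S17 left out of the rest, a choice made after seeing the data, differences were larger, with log2 9.91 for ATHB8, 8.85 for ACL5, 6.98 for PXY, 6.04 for XCP2, 5.78 for VND6, 4.91 for CESA8, 6.72 for BAM3 and 4.68 for CYP94B3. Lower genes were at -7.23 for FAR1, -6.24 for ABCG13, -5.51 for KCS1, -5.13 for PDF1 and -5.85 for HMGB9. Without AtHB8 replicate 2 FAR1 was at log2 -7.28, ABCG13 at -4.62 and HMGB9 at -4.23. FAR1 was at -5.47 without AtHB8 replicate 3, and HMGB9 at -5.65 without AtHB8 replicate 1. The ubiquitin 3' to 5' ratio was 2.05 ± 0.343 (SD, n = 6) on AtHB8 and S17 arrays and 3.40 ± 0.696 (n = 13) on the others (exact permutation p = 0.00059, adjusted p = 0.00354), a difference shared by the xylem and phloem comparisons. AtHB8 and S17 had the lowest means of all reporters, and the adjustment does not cover a choice among reporters. The other 4 ratio tests did not pass. With the 60th percentile filter the auxin (adjusted p = 0.0739), meristem (adjusted p = 0.204) and xylem secondary wall lists (adjusted p = 0.051) did not pass. The photosynthesis list did not pass without AtHB8 replicate 3 (adjusted p = 0.0604) or with fry (adjusted p = 0.0788).

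Phloem cells (S17, n = 3) expressed sugar and amino acid exporters at high levels. SWEET11, a sucrose exporter of phloem parenchyma, was 227-fold higher (log2 7.83 ± 0.40 SE, adjusted p = 8.11e-10), with a signal of 19064 ± 555 (SD, n = 3). SWEET12 was at least 211-fold higher (log2 8.03 ± 0.40), UMAMIT28, an amino acid exporter, at least 110-fold, and BZIP9, a leucine zipper factor of the phloem, at least 213-fold. The companion cell genes SUC2, a sucrose-proton symporter (adjusted p = 2.77e-09), and AHA3, a proton pump (13.2-fold), were higher, as was BZIP6, at least 5.10-fold (log2 2.38 ± 0.31). The ratios of arithmetic means, chosen after seeing the data, were 4.72 for BZIP6 and 53.0 for UMAMIT28. Of 23 phloem genes 19 were higher (camera adjusted p = 1.93e-09, and adjusted p = 0.00815 with an estimated correlation). F3H, a flavanone hydroxylase, was 46.6-fold lower (log2 -5.54 ± 0.29, adjusted p = 1.15e-09), and CHIL, a chalcone isomerase-like gene, at least 14.0-fold (log2 -4.91, and -5.53 without S17 replicate 1).

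Photosynthesis genes were higher in 14 of 22 cases, with GAPA 4.86-fold and PRK 3.53-fold (camera adjusted p = 3.05e-07, adjusted p = 0.316 with an estimated correlation). Procambium and early xylem genes were higher in 7 of 10 and lower in 1, with ATHB8 at least 21.1-fold, PXY at least 13.7-fold and CNA 7.14-fold higher (adjusted p = 0.000393, adjusted p = 0.157 with an estimated correlation). Xylem secondary wall genes were higher in 6 of 11, or 7 adjusted over the list alone, with XCP2 at least 6.31-fold (adjusted p = 0.00828, adjusted p = 0.287 with an estimated correlation). Stress and wounding genes, set as a mark of the protoplasting, were higher in 7 of 20 and lower in 1, with CYP94B3 11.3-fold and the jasmonate synthesis gene OPR3 3.76-fold (adjusted p = 0.0142, adjusted p = 0.382 with an estimated correlation). Here too handling of the cells is not separated from cell type. The ratios of arithmetic means were 1.10 for ATHB8, 1.69 for PXY, 2.88 for CNA, 1.25 for XCP2 and 3.68 for CYP94B3, as AtHB8 was above S17 in all 5. Abaxial genes did not pass (2 of 6 higher, 1 lower, adjusted p = 0.648), although KAN3 was at least 7.34-fold and KAN2 at least 4.84-fold higher.

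Cell division genes were lower in 18 of 22 cases in the phloem, with CYCB1;1 5.27-fold (log2 -2.40 ± 0.17 SE, camera adjusted p = 3.45e-08, adjusted p = 0.157 with an estimated correlation). Genes of cuticle and wax were lower in 16 of 18, with FDH 23.9-fold (adjusted p = 4.86e-10, and adjusted p = 0.00569 with an estimated correlation), and epidermal identity genes in 10 of 11 (adjusted p = 7.88e-06, adjusted p = 0.0529 with an estimated correlation). Boundary genes were lower in 11 of 14 and higher in 1 (adjusted p = 0.00197, adjusted p = 0.0765 with an estimated correlation), and HMG box genes in 7 of 12, with 1 higher (adjusted p = 0.00943, adjusted p = 0.202 with an estimated correlation). ULT1 was 24.1-fold lower (log2 -4.59 ± 0.14), UFO at least 10.1-fold and LFY, the floral identity regulator, 4.96-fold, while the floral list did not pass (2 of 12 higher, 4 lower, adjusted p = 0.428). In all, 2112 probe sets were higher and 1815 lower, and with no fold minimum the larger side turned (3630 higher and 4854 lower). With AtHB8 left out of the rest, a choice made after seeing the data, differences were larger, with log2 9.25 for UMAMIT28, 7.46 for ATHB8, 5.22 for PXY, 3.54 for CNA, 3.90 for XCP2, 4.27 for CYP94B3 and -5.47 for FDH. The xylem secondary wall list did not pass in the phloem with the 60th percentile filter (adjusted p = 0.262).

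**Figure D3:**
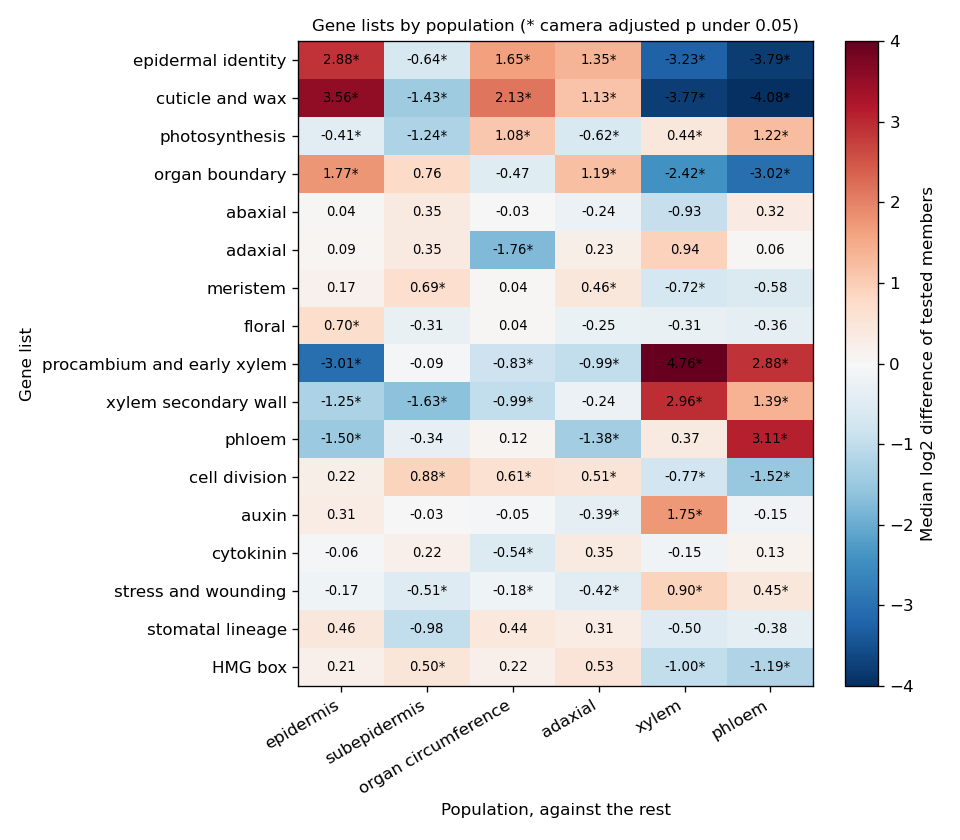
Median log2 difference of the tested members of 17 gene lists (vertical) in 6 cell types against the rest (horizontal), coloured from lower (blue) to higher (red), with a star where the camera adjusted p is under 0.05. Cuticle and wax genes have medians of 3.56 in the epidermis and -4.08 in the phloem, and phloem genes a median of 3.11 in the phloem.

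AtML1 (n = 2) and HMG (n = 3) both stand for the epidermis and were compared to see how far they differ. KNAT1 was 5.97-fold higher in AtML1 (log2 2.58 ± 0.19 SE, adjusted p = 7.93e-06), with signals of 743 ± 51.1 and 124 ± 8.56. TIP2, a tonoplast aquaporin, was 31.6-fold higher (log2 4.98 ± 0.74, adjusted p = 0.00194). Lower in AtML1 was MED31, a Mediator subunit gene, at least 2.81-fold (log2 -2.89 ± 0.31, adjusted p = 0.00032). Cell division genes were lower in 4 of 22 cases (camera adjusted p = 0.00135, adjusted p = 0.374 with an estimated correlation), and photosynthesis genes higher in 2 of 22, or 5 adjusted over the list alone (adjusted p = 0.000501, adjusted p = 0.487 with an estimated correlation). Epidermal identity (0 of 11, adjusted p = 0.411) and cuticle and wax genes (0 of 18, adjusted p = 0.648) had no called member.

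The number of genes called for AtML1 against HMG, 408 higher and 351 lower in AtML1, depended on the arrays and the fit. It was 9 when only the 5 arrays compared were fitted, 1335 with array weights, 1339 without the 3 arrays of highest actin ratio (chosen after seeing the data), 364 and 385 without AtML1 replicate 1 or 3, 1190 without HMG replicate 1 and 452 without HMG replicate 3. The higher and lower sides were 8 and 1 with those 5 arrays alone, 789 and 546 with array weights, and 798 and 541 without the 3 arrays. They were 130 and 234 without AtML1 replicate 1, 151 and 234 without AtML1 replicate 3, 698 and 492 without HMG replicate 1, and 212 and 240 without HMG replicate 3. The larger side thus turned without either AtML1 array or HMG replicate 3, and also with quantile normalisation (316 and 363) and with no fold minimum (779 and 824). TIP2 was at log2 5.92 without HMG replicate 2, 3.96 without HMG replicate 3 and 3.63 with array weights. With only those 5 arrays TIP2 (adjusted p = 0.134) and MED31 (adjusted p = 0.101) were not called. Without AtML1 replicate 3 neither the cell division list (adjusted p = 0.0744) nor the photosynthesis list (adjusted p = 0.0705) passed. With fry the photosynthesis list did not pass (adjusted p = 0.092).

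Epidermis (n = 5) and subepidermis (HDG4, n = 3) were compared directly as adjacent layers. PDF2, the close relative of ATML1, was 36.3-fold higher in the epidermis (log2 5.18 ± 0.37 SE, adjusted p = 1.19e-07), FDH 32.7-fold, ATML1 25.4-fold and OFP15 at least 49.8-fold. In the subepidermis BAM3 was at least 20.4-fold (log2 -6.30 ± 0.50), SEOR1 at least 33.1-fold, APL at least 6.91-fold and CYCB1;1 2.47-fold higher than in the epidermis. In the epidermis cuticle and wax genes were higher in 17 of 18 cases (camera adjusted p = 7.44e-24, and adjusted p = 0.000342 with an estimated correlation), and epidermal identity genes in 8 of 11, with 1 lower (adjusted p = 5.21e-09, and adjusted p = 0.0194 with an estimated correlation). Photosynthesis genes were higher in 7 of 22 (adjusted p = 1.26e-05, adjusted p = 0.374 with an estimated correlation) and stress and wounding genes in 1 of 20 (adjusted p = 0.0172, adjusted p = 0.393 with an estimated correlation).

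Lower in the epidermis than in the subepidermis were 5 of 10 procambium and early xylem genes (camera adjusted p = 0.000234, adjusted p = 0.149 with an estimated correlation) and 4 of 22 cell division genes (adjusted p = 0.000742, adjusted p = 0.354 with an estimated correlation). Phloem genes were lower in 7 of 23 cases, or 8 with 1 higher adjusted over the list alone (adjusted p = 0.0162, adjusted p = 0.189 with an estimated correlation). In all, 862 probe sets were higher and 598 lower in the epidermis, and with no fold minimum the larger side turned (1423 higher and 1666 lower). OFP15 was at log2 5.69 without HDG4 replicate 1, against 6.56, and BAM3 at -6.89 with array weights and -7.27 without the 3 arrays of highest actin ratio, a set chosen after seeing the data. The phloem list did not pass with the 60th percentile filter (adjusted p = 0.0857). The stress list did not pass with only the arrays compared (adjusted p = 0.0596), without the 3 arrays of highest actin ratio (adjusted p = 0.0618), without HDG4 replicate 3 (adjusted p = 0.084) or without HMG replicate 1 (adjusted p = 0.0914).

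Xylem (AtHB8) and phloem (S17, n = 3 each) differed in transporters of sucrose and in auxin genes, among others. SWEET11 was 393-fold lower in xylem (log2 -8.62 ± 0.52 SE, adjusted p = 1.17e-07), SWEET12 at least 248-fold, AHA3 17.1-fold and SUC2 11.4-fold. MP, an auxin response factor, was 10.2-fold higher in xylem (log2 3.35 ± 0.25, adjusted p = 5.98e-07), TMO5 8.78-fold, LAX2 7.81-fold and PHB 4.25-fold. KAN2, an abaxial and phloem-side regulator, was at least 14.4-fold lower in xylem. Phloem genes were lower in 12 of 23 cases and higher in 1, or 13 and 2 adjusted over the list alone (camera adjusted p = 6.62e-08, and adjusted p = 0.0141 with an estimated correlation). Auxin genes were higher in 6 of 12 and lower in 1, or 7 higher adjusted over the list alone (adjusted p = 4.75e-05, and adjusted p = 0.0153 with an estimated correlation). Procambium and early xylem genes were higher in 7 of 10, with 1 lower adjusted over the list alone (adjusted p = 7.69e-05, adjusted p = 0.12 with an estimated correlation).

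Xylem secondary wall genes were higher in xylem than in phloem in 1 of 11 cases, or 4 adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.22 with an estimated correlation). Higher shifts were also found for adaxial genes (2 of 6, adjusted p = 0.0365, adjusted p = 0.287 with an estimated correlation), cell division genes (4 of 22, or 5 adjusted over the list alone, adjusted p = 2.55e-05, adjusted p = 0.266 with an estimated correlation) and stress and wounding genes (1 of 20, or 2 adjusted over the list alone, adjusted p = 0.0115, adjusted p = 0.374 with an estimated correlation). Photosynthesis genes were lower in 2 of 22, or 3 adjusted over the list alone (adjusted p = 3.88e-06, adjusted p = 0.359 with an estimated correlation). In all, 637 probe sets were higher and 660 lower in xylem, and with no fold minimum the larger side turned (1298 higher and 1060 lower). KAN2 was at log2 -5.42 without AtHB8 replicate 2 and -3.79 without AtHB8 replicate 3, against -4.74. With the 60th percentile filter the xylem secondary wall (adjusted p = 0.199) and adaxial lists (adjusted p = 0.0576) did not pass. With quantile normalisation the stress list did not (adjusted p = 0.093). The adaxial list did not pass without AtHB8 replicate 2 (adjusted p = 0.0551) or 3 (adjusted p = 0.0667) or without S17 replicate 2 (adjusted p = 0.0943).

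**Figure D4:**
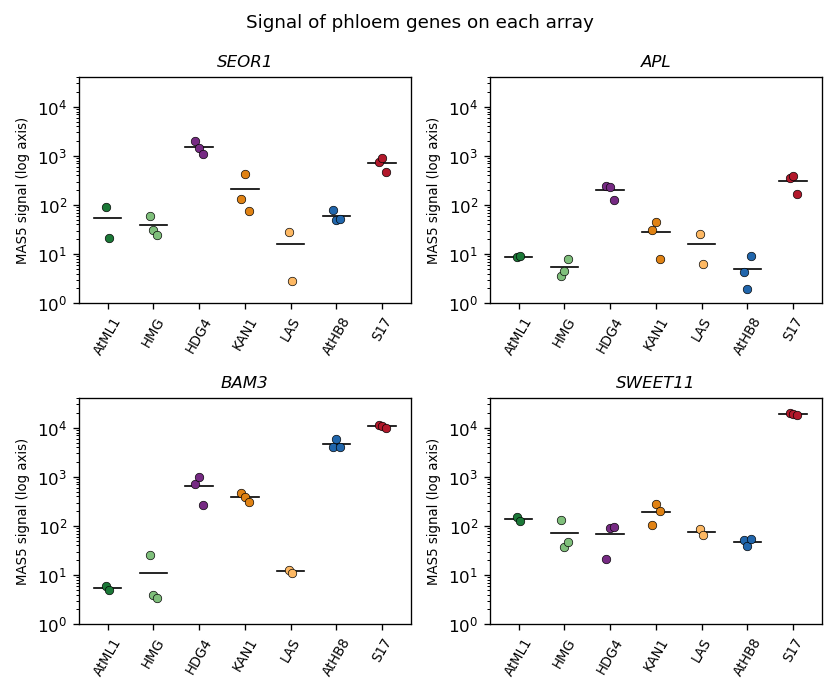
MAS5 signal (log axis) of SEOR1, APL, BAM3 and SWEET11 on each array, grouped by reporter, with lines at the means. SWEET11 is high in S17 with a mean of 19064 and at 68.4 in HDG4, while SEOR1 has a mean of 1516 in HDG4 and 711 in S17.

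Organ circumference (KAN1, n = 3) and adaxial cells (LAS, n = 2) were compared as different sides and zones of the apex. LAS was 66.1-fold lower in KAN1 (log2 -6.05 ± 0.50 SE, adjusted p = 4.9e-06), STM 4.19-fold and AGO7, which acts in adaxial patterning, 5.24-fold. KNAT1 was 5.78-fold higher (log2 2.53 ± 0.19, adjusted p = 1.34e-06), FIL 4.78-fold, RCA, the Rubisco activase, 4.50-fold and SUC2 5.64-fold. Photosynthesis genes were higher in 17 of 22 cases, or 18 adjusted over the list alone (camera adjusted p = 1.72e-15, adjusted p = 0.149 with an estimated correlation). Phloem genes were higher in 8 of 23, or 9 adjusted over the list alone (adjusted p = 0.000241, adjusted p = 0.0541 with an estimated correlation), and cuticle and wax genes in 3 of 18 (adjusted p = 6.45e-05, and adjusted p = 0.0397 with an estimated correlation).

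Boundary genes were lower around the organ circumference than in adaxial cells in 8 of 14 cases, or 9 adjusted over the list alone, with JLO at least 10.5-fold (camera adjusted p = 3.97e-05, and adjusted p = 0.0266 with an estimated correlation). Adaxial genes were lower in 4 of 6 (adjusted p = 0.00346, adjusted p = 0.166 with an estimated correlation) and cytokinin genes in 3 of 10, with the cytokinin-activating enzyme LOG7 3.04-fold (adjusted p = 0.028, adjusted p = 0.168 with an estimated correlation). In all, 1094 probe sets were higher and 569 lower, and 1104 were called in total, 279 of them lower, without LAS replicate 1. JLO was at log2 -4.10 without LAS replicate 1 or without the 3 arrays of highest actin ratio, and at -2.90 without LAS replicate 2, against -3.50. The cytokinin list did not pass without LAS replicate 1 (adjusted p = 0.0649) or without the 3 arrays of highest actin ratio (adjusted p = 0.101).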

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

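The tests of carry-over and of scaling were chosen only after the results were seen, while the single-array check and the regroupings were planned. Among the 5 epidermal arrays, 23 genes were checked for an array far from the others by Dixon's test, and 2 were marked, where chance marks about 1 in 20. ATML1 was highest on HMG replicate 3 at 10344 (the next array was at 7963). KCS1 was highest on HMG replicate 1 at 9106 (the next was at 6886).

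Epidermal and cuticle genes were high on the KAN1 arrays, where 22 called members had a median of 67.0% of their epidermal signal. Quantile normalisation left their median log2 difference at 2.30, against 2.29. Array medians of tested probe sets spanned only 0.11 on the log2 scale beforehand, so this test could hardly come out otherwise. It is no separate support against the scaling of the arrays. Of 63 genes abundant in epidermal cells and low in HDG4, AtHB8 and S17, 6.35% lay under 33.5%, the limit for a carry-over, with the highest KAN1 array taken over the lowest epidermal array, and 23.8% (15 genes) with mean over mean, where the median share was 48.8%. Of the members, 2 were higher on every KAN1 array than on every epidermal array, HDG1 (985 against 487) and CER1 (2177 against 1382), as were 2 of the 63 genes, among them ALF5 (1498 against 1149), and carry-over alone cannot give these values. They are too few to decide on the other members, for which carry-over and expression in the cells of the KAN1 reporter may each account.

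Sieve element genes were high on the HDG4 arrays, with SEOR1 at 1516 against 711 in S17, SEOR2 at 743 against 377, CALS7 at 169 against 58.3, APL at 202 against 301 and BAM3 at 655 against 10722. BAM3 was higher in AtHB8 too, at 3982 to 5894 per array. In KAN1 it lay at 301 to 466, which overlaps the 268 to 975 of HDG4, so BAM3 was not particular to HDG4. Carry-over of S17 cells is argued against: of 41 genes abundant in S17 and low outside S17 and HDG4, 100% lay under 33.5%, which is 50% of the share of APL (the lowest of the first 4 genes), and 61.0% lay under 3.05%, which is 50% of the share of BAM3, with the highest HDG4 array taken over the lowest S17 array. By the means their median share was 1.44%, with SWEET11 at 68.4 in HDG4 against 19064 in S17. Quantile normalisation gave a median log2 difference of 3.43, against 3.45. With array medians so close beforehand, this test too could hardly come out otherwise. Expression in the cells of the HDG4 reporter, or the presence of early phloem cells that S17 does not mark, may each account for the pattern, and neither was tested.

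Xylem and procambium genes were high on the S17 arrays, where 13 called members had a median of 24.1% of their AtHB8 signal. Their median log2 difference was 2.87 under quantile normalisation, against 2.84, which for the same reason does not decide on the scaling. Carry-over of AtHB8 cells was not excluded: of 104 genes abundant in AtHB8 and low outside AtHB8 and S17, 0% lay under the 12.1% limit with the highest S17 array taken over the lowest AtHB8 array, and 1 gene, NAC076 at 11.5%, with mean over mean, where the median share was 67.9%. By the means 31 of the 104 genes were higher in S17 than in AtHB8, 22 of them on every S17 array against every AtHB8 array, among them RUL1 (6452 against 1134) and HAM4 (7138 against 2324), as was the member XND1 (384 against 128), and carry-over cannot give these values. High shares of such genes are therefore no evidence for a carry-over either, and it and expression in the cells of the S17 reporter may each account for the rest of the pattern.

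For these 3 patterns, source genes had a mean of at least 1000 and at least 10 times the other populations, limits set after a stricter version with the LAS arrays included gave no gene, and before any share was seen. For the sieve element genes a first limit, at 50% of their median share of 197%, was dropped because any gene lower in HDG4 than in S17 meets it, and the genes were then divided into the 2 parts above, with the shares already seen. The comparison of every KAN1 array with every epidermal array was added after the shares of the members were seen.

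Other groupings of the arrays were tried for 7 comparisons. For the epidermis 2 of 100 groupings, the real one included, called as many probe sets (1918, highest other 2026). The subepidermis had 2 of 100 (1899, highest other 2049) and the organ circumference 4 of 100 (1144, highest other 3027). The xylem had 1 of 100 (3330, highest other 95), and the phloem 1 of 100 (3927, highest other 1995). For the epidermis against the subepidermis it was 1 of 56 (1460, highest other 546). Each of these shares lies under 0.05, but they were not adjusted over the 7 comparisons. The 100 groupings were a random draw that exchanged single arrays, whose replicates may be technical. A grouping that mixes reporters widens the spread within its groups, as arrays of the same reporter resemble each other. A low share therefore shows that resemblance and sets no chance level for a given comparison, so chance is not excluded by it. For the epidermis, subepidermis and organ circumference, other groupings also called more probe sets than the real one. The highest other grouping for the organ circumference called 3027 against the real 1144, and which arrays it put together was not examined. For xylem against phloem 1 of 10 groupings called as many (1297, highest other 3), and 10 groupings are too few for a share under 0.05.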

How the results depend on the processing

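The settings without the vascular reporters, with a filter on detection calls and without the 3 arrays of highest actin ratio were chosen after seeing the data, and the others were planned. Of 18219 values of 578 named gene results under the alternatives, 17676 kept direction and call, 531 lost the call and 12 turned. Of 2663 values of 79 list results, 2540 kept, 118 lost and 5 turned. Most values, 10982 for genes and 1501 for lists, came from leaving out single arrays. Only 394 of the 578 gene results and 19 of the 79 list results kept direction and call under every alternative. With no fold minimum the 10 counts were 5211 for epidermis, 5489 subepidermis, 3273 organ circumference, 3743 adaxial, 7777 xylem, 8484 phloem, 1603 AtML1 against HMG, 3089 epidermis against subepidermis, 2358 xylem against phloem and 2832 organ circumference against adaxial. This is by construction, as smaller differences enter. Without the vascular reporters in the rest, epidermis had 968, subepidermis 1196 and adaxial cells 541 calls. AtML1 against HMG had 1335 calls with array weights, 1339 without the 3 arrays of highest actin ratio and 9 when only the arrays compared were fitted. Of 79 list shifts, 19 remained with an estimated correlation. The cause was not tested except as stated.

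Leaving out each array in turn gave 1763 to 1970 calls for epidermis, 1563 to 2058 for subepidermis, 890 to 1176 for organ circumference, 1098 to 1665 for adaxial, 3138 to 3369 for xylem and 3760 to 3980 for phloem. It gave 364 to 1190 for AtML1 against HMG, 1248 to 1590 for epidermis against subepidermis, 1121 to 1356 for xylem against phloem, 1104 to 1744 for organ circumference against adaxial, 10809 to 11731 for the F test and 76 to 81 list shifts. Where a population was left with a lone array, it was assumed to vary like the others.

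All turned results came from leaving the vascular reporters out of the rest. The log2 differences became 0.11 for CESA8 and 0.19 for VND6 in the epidermis, -0.40 for CUC3 and 0.30 for CESA8 in the subepidermis, and 0.80 for ATHB8 and -0.24 for HMGB9 in the organ circumference. In adaxial cells they became -0.22 for ACR4, -0.21 for LTP1, -0.0333 for ATML1, -0.13 for HTH, -0.13 for FDH and -0.35 for CER3. Signed -log10 adjusted p-values of lists became -3.14 for cuticle and wax, -0.37 for epidermal identity and 0.35 for procambium and early xylem in adaxial cells, and 0.61 for procambium and early xylem and 0.33 for stress and wounding in the organ circumference.

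The replicate numbers do not pair the arrays: 46 same-number pairs had residual correlations of -0.227 to 0.206 (median 0.0043), 3 of them above 0.1, and 7 of 18 arrays correlated best with their own number. The fit with the replicate block called 1900 probe sets for epidermis, moved no count by over 1.5 times, and lost 18 of 578 gene calls and 2 of 79 list calls. Array medians of tested probe sets spanned 0.11 on the log2 scale, and 0.0026 under quantile normalisation. No scaling moved the share of higher calls by over 10 percentage points. With no fold minimum that share was 47.6% in place of 37.2% for epidermis, 54.5% in place of 32.4% for subepidermis, 58.6% in place of 67.0% for organ circumference and 53.5% in place of 33.2% for adaxial. It was 44.6% in place of 58.1% for xylem, 42.8% in place of 53.8% for phloem and 48.6% in place of 53.8% for AtML1 against HMG. It was 46.1% in place of 59.0% for epidermis against subepidermis, 54.6% in place of 65.8% for organ circumference against adaxial, and for xylem against phloem 1298 were higher and 1060 lower in place of 49.1% higher. The larger side thus turned in 7 of the 10. A pseudocount of 32 shrank the differences of dim genes by construction. For dim genes the signal over background limits the size of a difference to a bound.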

Other observations

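Genes in this part were chosen only after their values were seen, and no test of a family is given: tests made at first were dropped for that reason. Families of transporters named by their symbols were examined because SWEET11, SWEET12 and UMAMIT28 were high in the phloem cells, so the counts include these genes. In the UMAMIT family of amino acid exporters, 17 of 23 tested members were higher in S17 against the rest and 0 lower, and 8 were higher and 2 lower in AtHB8. In the AAP family of amino acid permeases 6 of 7 tested members were higher in S17 and 4 of 7 in AtHB8, with 0 lower. In the SWEET family of sugar transporters 5 of 7 tested members were higher in S17 and 0 lower, and 2 were higher and 2 lower in AtHB8. Of all 15149 tested probe sets, 2112 were higher and 1815 lower in S17, and 1934 higher and 1396 lower in AtHB8. Members that did not pass the filter are not counted, and a member high only in S17 could pass it through S17. Signals in S17 (SD, n = 3) were 4383 ± 442 for AAP7, 6737 ± 1300 for AAP6, 6141 ± 1132 for SWEET10 and 2581 ± 356 for UMAMIT30, against 88.1, 1893, 1036 and 130 in AtHB8. The nitrate transporter NRT1.7 was at 2922 ± 497 in S17 and 1176 ± 308 in AtHB8. AAP3 was higher in AtHB8, at 210 ± 46.7, than in S17, at 26.8 ± 14.0 (n = 3 each, limma adjusted p = 4e-04).

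Several genes of flavonol synthesis, picked by hand because F3H and CHIL were low in S17, were low in both vascular populations. TT4, TT5, TT7, F3H, FLS1, CHIL and MYB12 were each called lower in AtHB8 and in S17 against the rest, and no test of them as a set was made. TT4, the chalcone synthase at the head of the pathway, had signals of 144 ± 133 in AtHB8 and 137 ± 76.2 in S17 (SD, n = 3 each), against 12133 ± 4345 in AtML1 (n = 2) and 9460 ± 2187 in KAN1 (n = 3). FLS1, the flavonol synthase, was at 92.4 ± 82.6 in AtHB8 and 33.0 ± 21.3 in S17, against 7260 ± 2742 in AtML1. MYB12, which activates these genes, was at 58.1 ± 29.2 and 51.2 ± 20.8, against 1350 ± 609 in AtML1.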
